A study of Mus musculus with 6 samples.

How the data were processed

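Liver RNA of 3 samples labelled WT and 3 labelled Hnrnpu-cKO had been enriched for polyadenylated RNA and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The deposited table holds whole-number read counts per gene, not normalised, with one column for each of the 6 samples and totals of 15860807 to 20803317. The authors made these counts with HISAT2, featureCounts and Subread on the mm10 build, per the submitters' processing notes, which give no version, role or order; the annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies can therefore not be told apart, and PCR copies were not marked by molecular identifiers, so intervals and floors cover counting error only. Each column was matched to the sample whose description gives the same name, and 0 columns were left without a sample. No 2 columns were identical. Of 54532 gene identifiers, 54495 matched GENCODE release M21, an annotation of the same build, from which coordinates, strand and gene type were taken.

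Genes were kept by edgeR's filterByExpr with the genotype as group, which left 14847, and libraries were scaled by TMM (factors 0.649 to 1.69). The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with genotype as the only term over all 6 samples, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors were computed as the absolute log2 fold change divided by the square root of F. CPM values are counts over the TMM-scaled library size, as given by edgeR's cpm function. A gene with 0 counts in a whole group was given a fold against 3 counts in each library of that group, and the ratio of a gene with 1 to 3 counts was given with an exact binomial 95% interval. Counts were simulated for the 14847 genes with the observed spread and 200 changed genes, besides a further list of genes raised by 2 on the log2 scale. Of the 200, the test called 0%, 4%, 28% and 44% of genes changed by 1, 2, 3 and 4 on that scale. It made 2 false calls among 42, with calls on the further list counted as true. With the spread reduced and without that list it called 46%, 72%, 94% and 100% of the changed genes.

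Before the data were examined, 46 lists with 1428 genes were fixed for liver functions, zonation, proliferation, stress, RNA processing, sex and other cell types, of which 45 had at least 3 tested genes. They were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, and again with the correlation estimated for each list and with fry, which asks whether the genes of a list move on balance one way. Genes were named by a rule fixed at the same time: Hnrnpu; Ntrk2, Bdnf, Cdkn1a, Ccnd1, Mki67, Afp, Alb, Hnf4a and Tnf whatever their values; the 8 largest rises and 8 largest falls among called genes of at least 5 CPM in the higher group whose groups did not overlap, leaving out predicted, clone, pseudogene and receptor segment names; at most 4 members of a described list with the smallest p in its direction and at most 2 in the other; and Xist with the Y-linked genes. Not every gene that this rule allows is reported here. Alternatives fixed before the data were examined were RLE and upper quartile scaling, no filter beyond 1 count, at least 5 CPM in 3 samples, leaving out mitochondrial genes and the 10 most abundant, the replicate number as a block, DESeq2 1.42.0, limma-voom, stricter thresholds and leaving out each sample. Total-count scaling, a mean of at least 20 CPM, a robust quasi-likelihood fit and voom with sample quality weights were added after seeing the data. Libraries were compared for detected genes after drawing 7395974 counts outside the mitochondrial genes from each at random without replacement. Splicing was not analysed here, since the counts are per gene.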

Results

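RNA-seq read counts were compared between livers of wild-type mice and livers of mice with a hepatocyte-specific knockout of Hnrnpu, in a series on the function of this gene in liver regeneration. Hnrnpu encodes an RNA-binding protein of the hnRNP family that takes part in pre-mRNA splicing and chromatin organisation. Polyadenylated RNA was sequenced from 3 samples labelled WT and 3 samples labelled Hnrnpu-cKO, and each sample had a whole-number read count for 54532 genes. The libraries held 15860807 to 19942270 counts in the group labelled WT and 18382802 to 20803317 in the group labelled Hnrnpu-cKO. The labels gave no operation, time point, sex, age or pairing, and nothing on whether the samples came from separate animals, so p-values measure only the spread between these samples.

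The targeted gene was higher, not lower, in the libraries labelled Hnrnpu-cKO. Hnrnpu (ENSMUSG00000039630) lies on chromosome 1 of the mm10 build, from 178321108 to 178337797 on the minus strand, and is a protein-coding gene. Its raw counts were 3253, 2131 and 2686 in WT replicates 1 to 3, and 12301, 11211 and 10267 in Hnrnpu-cKO replicates 1 to 3. After TMM normalisation the level was 207 ± 31.4 CPM (library-scaled counts; SD, n = 3) in the libraries labelled WT and 443 ± 97.5 CPM (SD, n = 3) in those labelled Hnrnpu-cKO. The log2 fold change was 1.10 (SE 0.30), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.0816, short of the threshold of 0.05. Every library labelled Hnrnpu-cKO lay above every library labelled WT, an outcome that chance gives in one direction or the other in 10% of comparisons of 3 against 3. As a percentage of the summed level of the other hnRNP family genes in the same library, Hnrnpu stood at 8.8 ± 1.7 (SD, n = 3) in WT and 15.9 ± 3.8 (SD, n = 3) in Hnrnpu-cKO. The deleted exons are not given in the sources used here and the counts are per gene, so they do not check the deletion itself. Cox20, on the other strand, overlaps the 3' end of Hnrnpu and had 39 counts at most in any library. Because the targeted gene goes against the labels, every direction that follows is a direction between libraries as labelled.

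**Figure D1:**
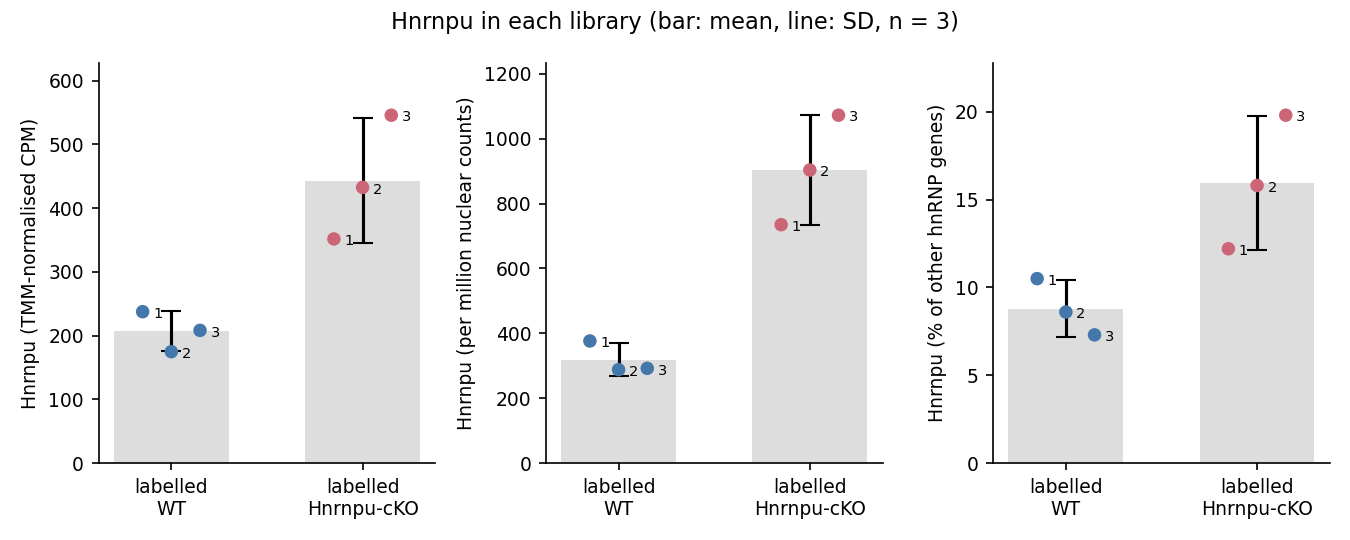
Hnrnpu in each of the 6 libraries as TMM-normalised CPM, scaled to the counts outside the mitochondrial genes, and as a percentage of the summed other hnRNP genes; points are libraries numbered by replicate, bars are means and lines are SD (n = 3). By each measure the 3 libraries labelled Hnrnpu-cKO lie above the 3 labelled WT (443 ± 97.5 against 207 ± 31.4 CPM).

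The libraries also differed between the groups in what they held. Mitochondrially encoded genes took 45.5%, 53.7% and 53.9% of the counts in WT replicates 1 to 3 and 19.5%, 35.4% and 47.9% in Hnrnpu-cKO replicates 1 to 3, so the groups overlapped. Genes of cytosolic ribosomal proteins took 1.56 ± 0.311% (SD, n = 3) of the remaining counts in WT and 4.51 ± 1.88% (SD, n = 3) in Hnrnpu-cKO, without overlap. When all libraries were thinned to 7395974 counts outside the mitochondrial genes, 11573 to 15318 genes were detected in the libraries labelled WT and 18135 to 20023 in those labelled Hnrnpu-cKO. Genes with 1 to 9 counts made up 3.87% to 12.5% of the detected genes in WT and 19.5% to 27.5% in Hnrnpu-cKO. Of the 9574 genes with at least 100 counts in every library labelled Hnrnpu-cKO, 73 had 0 counts in all 3 libraries labelled WT. Xist, the transcript of the inactive X chromosome, had 0, 0 and 21581 counts in WT replicates 1 to 3 and at most 21 counts in a library labelled Hnrnpu-cKO. The Y-linked gene Ddx3y stood at 132, 130 and 0 CPM in WT replicates 1 to 3 and at 73.0 to 90.1 CPM in the libraries labelled Hnrnpu-cKO, so WT replicate 3 had the female pattern and the other 5 libraries the male pattern.

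**Figure D2:**
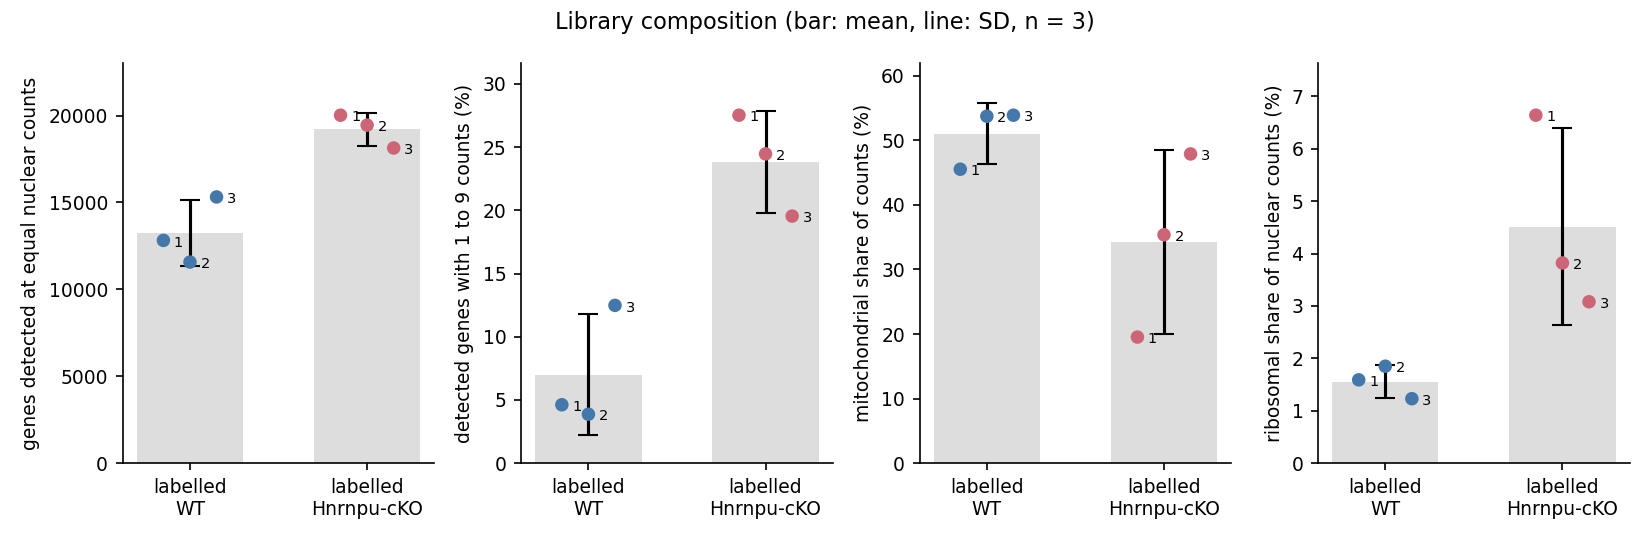
Composition of the 6 libraries: genes detected after thinning to equal counts outside the mitochondrial genes, the percentage of those genes with 1 to 9 counts, the mitochondrial percentage of all counts, and the ribosomal protein percentage of the remaining counts; points are libraries numbered by replicate, bars are means and lines are SD (n = 3). The groups do not overlap in detected genes (11573 to 15318 against 18135 to 20023), while their mitochondrial percentages overlap.

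In the libraries labelled Hnrnpu-cKO, the amino acid enzyme Oat fell from 1264 ± 279 to 78.4 ± 25.9 CPM (SD, n = 3) and Cyp8b1, of bile acid synthesis, from 218 ± 59.5 to 7.72 ± 4.63 CPM. H19, a fetal RNA, rose at least 2200-fold and Foxm1, a regulator of mitosis, at least 113-fold. By limma's camera test with a preset correlation, 10 fixed gene lists were higher and 16 lower of 45 tested, but 0 lists were called with an estimated correlation. By fry 14 lists were called. Of 14847 tested genes, 113 were higher and 91 lower in Hnrnpu-cKO at an adjusted p under 0.05, with a median log2 fold change of 4.55 among the higher and -2.61 among the lower. Of the 113 higher genes, 43 had 0 counts in all 3 libraries labelled WT, so that their folds were computed against a floor of 3 counts per library (0.233 CPM on average). Here and below, a fold given as "at least" is a lower bound for counting error only, since a 0 in these libraries was no firm absence. In all 204 called genes the 2 groups did not overlap, as in 5125 tested genes (34.5%). Chance alone gives 10% on average, but genes of a library move together, so a single split can lie far from that average. The smallest adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.0247, and 3113 genes (21%) had an unadjusted p under 0.05. With total-count scaling, chosen after seeing the data, the median log2 fold change of all tested genes moved from 0.22 to 1.07, a shift of 0.85, and the split of calls moved from 113 higher and 91 lower (55.4% higher) to 1732 and 127 (93.2% higher). When 1 library was left out, edgeR's test called 0 genes without Hnrnpu-cKO replicate 1, 2 or 3 (2409, 2314 and 3138 at an unadjusted p under 0.05). It called 3 without WT replicate 1, 147 without WT replicate 2 (106 of the 204 among them) and 108 without WT replicate 3 (61 of the 204). The fold changes of all 204 genes kept their sign in each fit, which the lack of overlap between the groups all but fixed in advance.

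Among the largest rises, H19, an imprinted long non-coding RNA of fetal tissue, went from 0 counts in every library labelled WT to 511 ± 203 CPM (SD, n = 3), at least 2200-fold higher. Gsta1, a glutathione S-transferase, was at least 521-fold higher at 121 ± 29.2 CPM. Phgdh, the first enzyme of serine synthesis, was at least 407-fold higher, and Asns, asparagine synthetase, at least 307-fold higher. Bex2 rose at least 354-fold, Vmn2r3, of a family of vomeronasal receptors, at least 208-fold, and Wfdc3 at least 168-fold. Sprr1a, a small proline-rich protein of squamous epithelia, was at least 762-fold higher. Hnrnpu-cKO replicate 1 had the highest level of Sprr1a, Phgdh, Bex2, Asns, Vmn2r3 and Wfdc3, and without it their bounds were 290, 254, 191, 179, 111 and 93.9. These 8 genes had adjusted p from 0.0247 to 0.0448 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). In libraries labelled WT a count of 0 was no firm absence: of the genes with at least 100 counts in both other WT libraries, 36, 205 and 7 were at 0 in replicates 1, 2 and 3, against 0, 0 and 1 in Hnrnpu-cKO, and the floor covers counting error only.

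Major urinary proteins, liver-secreted pheromone carriers, made up 6 of the 8 largest falls. Mup17 fell from 3628 ± 3257 to 0.469 ± 0.746 CPM (SD, n = 3), Mup3 from 3106 ± 1910 to 17.6 ± 13.6 CPM, Mup21 from 133 ± 115 to 0.505 ± 0.191 CPM, Mup15 from 101 ± 84.8 to 0.0643 ± 0.111 CPM and Mup13 from 34.8 ± 4.63 to 0.102 ± 0.144 CPM. Mup1 had 930 counts over the libraries labelled WT and 1 count over those labelled Hnrnpu-cKO, a ratio of 1910 (95% exact counting interval 342 to 75600). The Mup genes are near-identical copies among which reads can be split, so the values of single members are uncertain. Several Mup genes are higher in male mice, and the female-pattern WT replicate 3 held 368 CPM of Mup17 against 6882 and 3633 CPM in WT replicates 1 and 2. The sulfotransferase gene Sult2a8 (log2 fold change -6.55, SE 0.85) and the cytochrome P450 gene Cyp2c54 (-6.22, SE 0.99) completed the list, and the 8 genes had adjusted p from 0.0247 to 0.0463 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

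**Figure D3:**
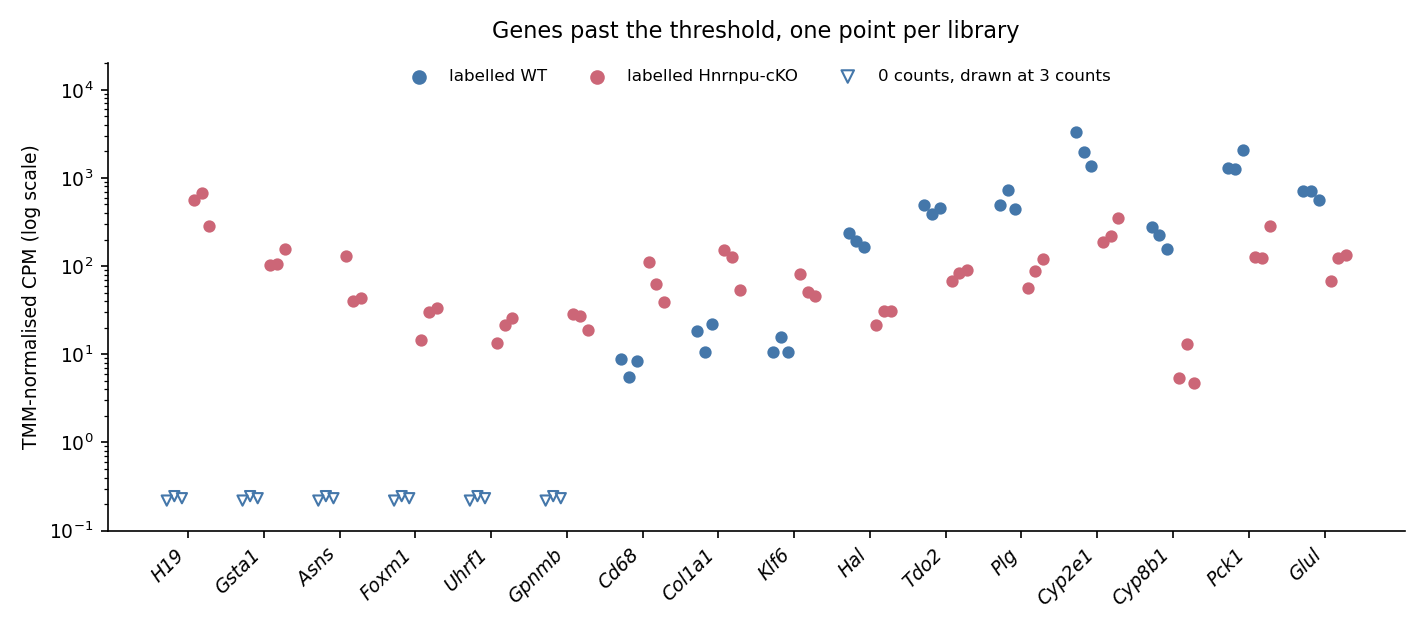
TMM-normalised CPM on a log axis of 16 genes that passed the threshold, one point per library; open triangles are libraries with 0 counts, drawn at the level of 3 counts. H19, Gsta1, Asns, Foxm1, Uhrf1 and Gpnmb had 0 counts in all 3 libraries labelled WT, and the 7 genes from Hal to Glul were lower in every library labelled Hnrnpu-cKO.

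Enzymes of amino acid metabolism and proteins secreted into plasma had the lowest p-values among the lists. Of 35 tested genes of the urea cycle and amino acid breakdown, 0 were higher and 9 lower over all genes, 0 and 25 adjusted over the list alone, with a median log2 fold change of -1.70, or -0.98 with total-count scaling. Oat, ornithine aminotransferase, fell from 1264 ± 279 to 78.4 ± 25.9 CPM (SD, n = 3). Hal (histidine ammonia-lyase, log2 fold change -2.84, SE 0.30), Tdo2 (tryptophan dioxygenase, -2.48, SE 0.28) and Agxt (-2.33, SE 0.27) also fell, each with an adjusted p of 0.0247 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The list was lower by limma's camera test with a preset correlation of 0.01 (adjusted p = 4.07e-24), which did not hold in the stricter form (adjusted p = 0.238 with an estimated correlation). Of 54 plasma protein genes, 0 were higher and 6 lower, 0 and 35 adjusted over the list alone. Their median was -1.50, or -0.77 with total-count scaling (camera adjusted p = 3.9e-27, adjusted p = 0.238 with an estimated correlation). Plg, the precursor of plasmin, fell (log2 fold change -2.65, SE 0.40), as did Serping1 (-2.11, SE 0.33) and Fetub (-2.36). Alb stood at 37700 ± 35860 CPM in WT and 16430 ± 10440 CPM in Hnrnpu-cKO (SD, n = 3, adjusted p 0.624 by the same edgeR test). The WT mean rested largely on replicate 3, at 78630 CPM against 11780 and 22690 CPM in WT replicates 1 and 2. Of 31 acute phase genes, 0 were higher and 4 lower, 3 and 14 adjusted over the list alone. The list median was -1.03, or -0.27 with total-count scaling and -1.56 with a mean of at least 20 CPM (camera adjusted p = 8.2e-06, adjusted p = 0.238 with an estimated correlation). Those that fell were Lbp, Fgl1, Itih3 and Itih4 (log2 fold changes -2.69, -3.17, -2.79 and -2.60). Hamp, which encodes the iron hormone hepcidin, stood at 362 ± 97.1 CPM in WT and 1018 ± 24.9 CPM in Hnrnpu-cKO without passing the test (adjusted p 0.0675, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

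Lipid, bile acid and drug metabolism followed. Of 34 genes of fatty acid oxidation, 0 were higher and 1 lower over all genes, Acaa1a (log2 fold change -1.97, SE 0.28), and 2 and 22 adjusted over the list alone. As a set they had a median of -1.19, or -0.35 with total-count scaling (camera adjusted p = 5.17e-16, adjusted p = 0.238 with an estimated correlation). Cpt1a, the entry enzyme of mitochondrial oxidation, had a log2 fold change of -1.37 (SE 0.25) and an adjusted p of 0.054 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 18 genes of bile acid synthesis, 0 were higher and 1 lower, 1 and 9 adjusted over the list alone. Across members the median was -1.15, or -0.37 with total-count scaling (camera adjusted p = 9.35e-06, adjusted p = 0.298 with an estimated correlation). The gene that fell was Cyp8b1, sterol 12-alpha-hydroxylase, from 218 ± 59.5 to 7.72 ± 4.63 CPM (SD, n = 3). Of 48 cytochrome P450 and conjugation genes, 1 was higher and 4 lower, 3 and 23 adjusted over the list alone. Their median was -1.30, or -0.61 with total-count scaling (camera adjusted p = 5.73e-10, adjusted p = 0.298 with an estimated correlation). Cyp2e1 fell from 2217 ± 991 to 252 ± 87.0 CPM (SD, n = 3) and Cyp2c37 and Ugt2b1 fell as well (log2 fold changes -5.19 and -2.96). The carboxylesterase Ces1g rose (1.62). The Cyp2c, Ugt2b and Ces1 families are made of similar copies, so the values of single members are uncertain. Of 20 genes of bile acid and organic anion transport, 0 were higher and 1 lower (Slco1a1, log2 fold change -5.95, SE 0.76), 2 and 10 adjusted over the list alone. The list median was -0.76 and became 0.01 with total-count scaling, -1.40 with a mean of at least 20 CPM and -1.36 with at least 5 CPM in 3 samples (camera adjusted p = 0.000861, adjusted p = 0.313 with an estimated correlation).

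Zoned genes of the liver lobule changed at both of its ends, with falls in Hal and Pck1 on the portal side and Glul and Oat on the central side. Of 24 periportal genes, 1 was higher and 2 lower, 1 and 11 adjusted over the list alone. As a set they had a median of -1.20, or -0.38 with total-count scaling (camera adjusted p = 1.99e-08, adjusted p = 0.262 with an estimated correlation). Pck1, which controls entry into gluconeogenesis, fell from 1545 ± 444 to 179 ± 93.2 CPM (SD, n = 3) together with Hal, and Cdh1, which encodes E-cadherin, rose by 2.93 on the log2 scale (SE 0.37). Of 27 pericentral and Wnt-responsive genes, 1 was higher and 5 lower, 2 and 6 adjusted over the list alone (camera adjusted p = 0.00327, adjusted p = 0.319 with an estimated correlation). Glul, glutamine synthetase, fell from 661 ± 87.1 to 109 ± 36.1 CPM (SD, n = 3), with Oat, Lhpp (log2 fold change -2.99, SE 0.29) and the glutamate transporter Slc1a2 (-4.32, SE 0.68). Gstm3 rose from 1.52 ± 1.35 to 507 ± 254 CPM. From gene start to gene end, Oat and Lhpp overlap Fgfr2, Acaa1a overlaps Myd88, Plg overlaps Slc22a3 and Ccnd1 overlaps Oraov1. Whether their exons overlap was not examined. Their counts are uncertain while the use of strand is not known. Oat lies on the same strand as Fgfr2, so the use of strand would not settle its counts. The median of the pericentral list, -0.19, turned to 0.65 with total-count scaling, and was -0.78 with a mean of at least 20 CPM, -0.31 without WT replicate 1 and -0.38 without Hnrnpu-cKO replicate 3. Of 23 genes of gluconeogenesis and glycogen, 0 were higher and 1 lower (Pck1), 5 and 8 adjusted over the list alone. Across members the median was -0.40 and turned to 0.31 with total-count scaling, and it was -0.07 without Hnrnpu-cKO replicate 1 and -0.89 without Hnrnpu-cKO replicate 3 (camera adjusted p = 0.00156, adjusted p = 0.298 with an estimated correlation). Hepatocyte transcription factors gave 0 higher and 0 lower of 34 genes, also 0 and 0 adjusted over the list alone. Their median was -0.68 and turned to 0.12 with total-count scaling (camera adjusted p = 6.52e-07, adjusted p = 0.313 with an estimated correlation). Hnf4a stood at 236 ± 73.3 CPM in WT and 147 ± 51.8 CPM in Hnrnpu-cKO (adjusted p 0.374, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With total-count scaling these medians still lay below the median of all tested genes, 1.07.

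Among cell division genes, 12 of the mitosis list had 0 counts in all 3 libraries labelled WT, which also had few genes at low counts. All 35 tested mitosis genes had a positive log2 fold change, 8 were higher and 0 lower over all genes and 23 and 0 adjusted over the list alone. The list median was 5.06, or 4.47 with genes at 0 in WT set to their bounds (camera adjusted p = 5.84e-15, adjusted p = 0.238 with an estimated correlation). Foxm1, a transcription factor of the G2 and M phases, was at least 113-fold higher, the mitotic kinesin Kif11 at least 63.8-fold, Cdca8 at least 60.6-fold and the kinase Nek2 at least 50.5-fold. At these levels too a 0 in a library labelled WT was no firm absence, so the folds are not firm lower bounds. Of 34 DNA replication genes, 1 was higher and 0 lower, 12 and 0 adjusted over the list alone. As a set they had a median of 2.43 (camera adjusted p = 5.74e-07, adjusted p = 0.238 with an estimated correlation). Among genes with a mean of at least 20 CPM, a filter chosen after seeing the data, the replication list was not called (median 1.00, adjusted p 0.225) and the mitosis list had too few genes to test. The gene that passed was Uhrf1, which maintains DNA methylation at replication forks, at least 86.8-fold higher, and Mcm5, Lig1 and Mcm3 had log2 fold changes of 3.03, 2.45 and 2.40 without passing. Mki67 stood at 4.35 ± 4.98 CPM in WT and 97.0 ± 40.4 CPM in Hnrnpu-cKO (SD, n = 3; adjusted p 0.0828 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ccnd1, cyclin D1, stood at 1.37 ± 2.37 and 26.5 ± 4.50 CPM (adjusted p 0.181), and the cell cycle inhibitor Cdkn1a at 7.72 ± 11.6 and 79.2 ± 67.2 CPM (adjusted p 0.26, same edgeR test). The senescence list (secreted factors and cell cycle inhibitors) gave 0 higher and 0 lower of 19 genes, 3 and 0 adjusted over the list alone. Across members the median was 1.88, or 2.85 with total-count scaling (camera adjusted p = 0.00123, adjusted p = 0.261 with an estimated correlation). This call ended with at least 5 CPM in 3 samples (adjusted p 0.0645) and with a mean of at least 20 CPM (adjusted p 0.225).

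Of 29 fetal liver and imprinted genes, 7 were higher and 0 lower, 15 and 1 adjusted over the list alone. Their median was 3.90, or 3.52 with genes at 0 in WT set to their bounds (camera adjusted p = 1.09e-05, adjusted p = 0.238 with an estimated correlation). Besides H19, Ly6d rose (log2 fold change 6.33), and so did Rian, a non-coding RNA of an imprinted cluster, from 0.103 ± 0.179 to 95.6 ± 56.2 CPM (SD, n = 3), and the protease inhibitor Slpi, at least 160-fold (at least 94.7-fold without Hnrnpu-cKO replicate 1). Peg3 stood at 415 ± 481 CPM in WT and 78.0 ± 18.2 CPM in Hnrnpu-cKO without passing (adjusted p 0.141, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its WT mean rested largely on replicate 3, at 970.6 CPM against 148.5 and 125.4 CPM in WT replicates 1 and 2. Afp, alpha-fetoprotein, stood at 0, 0 and 3.96 CPM in the libraries labelled WT and at 242, 35.2 and 10.7 CPM in Hnrnpu-cKO replicates 1 to 3 (adjusted p 0.108, same edgeR test). Of 35 NRF2 and oxidative stress genes, 6 were higher and 0 lower, 20 and 1 adjusted over the list alone. The list median was 1.34, or 2.15 with total-count scaling (camera adjusted p = 6.39e-05, adjusted p = 0.238 with an estimated correlation). With Gsta1, the glutathione transferases Gsta2 (7.95 ± 2.01 to 60.0 ± 8.24 CPM, SD, n = 3) and Gstm3 and the pentose phosphate enzyme Pgd (20.1 ± 3.64 to 95.9 ± 12.9 CPM) rose, and catalase, Cat, had a log2 fold change of -1.15 (SE 0.33) without passing. The glutathione transferases are families of similar copies whose reads can be split. Of 27 immediate early genes, 3 were higher and 0 lower, 7 and 0 adjusted over the list alone. As a set they had a median of 2.17, or 0.97 with a mean of at least 20 CPM (camera adjusted p = 9.42e-05, adjusted p = 0.298 with an estimated correlation). The 3 that rose were Klf6 (log2 fold change 2.27, SE 0.34), Atf3 (4.57, SE 0.71) and Ier5 (2.81, SE 0.46). Bdnf and Tnf had 0 counts in every library labelled WT, and 87 and 129 counts over those labelled Hnrnpu-cKO. Against the floor of 3 counts per library they were 4.99-fold and 6.87-fold higher, both short of the threshold (adjusted p 0.0675, same edgeR test). At such low counts a 0 in a library labelled WT was no firm absence, so these folds are not firm lower bounds. The BDNF receptor gene Ntrk2 stood at 1.27 ± 1.64 CPM in WT and 8.08 ± 3.30 CPM in Hnrnpu-cKO (adjusted p 0.375, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

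Markers of other liver cells differed in their direction. Of 28 monocyte-derived macrophage genes, 3 were higher and 0 lower, 9 and 0 adjusted over the list alone. Across members the median was 1.24, or 2.15 with total-count scaling (camera adjusted p = 3.58e-05, adjusted p = 0.349 with an estimated correlation). Gpnmb was at least 108-fold higher, and the lysosomal glycoprotein gene Cd68 and Lgals3, galectin-3, rose by 3.22 (SE 0.45) and 4.25 (SE 0.73) on the log2 scale. Of 38 stellate cell and matrix genes, 3 were higher and 0 lower, 4 and 0 adjusted over the list alone. Their median was 1.23, or 2.20 with total-count scaling (camera adjusted p = 0.00327, adjusted p = 0.563 with an estimated correlation, and 0.0957 without WT replicate 3). The 3 were the fibrillar collagen genes Col3a1 (33.8 ± 12.2 to 227 ± 93.2 CPM, SD, n = 3), Col1a2 and Col1a1. Of 29 cholangiocyte genes, 0 were higher and 0 lower, 8 and 0 adjusted over the list alone. The list median was 1.60 (camera adjusted p = 0.00145, adjusted p = 0.299 with an estimated correlation, and 0.319 with a mean of at least 20 CPM). Endothelial markers gave 0 higher and 0 lower of 30, 0 and 0 adjusted over the list alone. As a set they had a median of -0.51, which turned to 0.33 with total-count scaling, below the median of all tested genes (camera adjusted p = 0.000256, adjusted p = 0.238 with an estimated correlation). The 11 erythroid genes gave 0 higher and 0 lower, 0 and 4 adjusted over the list alone. Across members the median was -2.14 (camera adjusted p = 0.000174, adjusted p = 0.298 with an estimated correlation). The 3 tested markers of pancreas or fat gave 0 higher and 0 lower, 0 and 2 adjusted over the list alone. The median of -1.18 became -0.37 with total-count scaling, -2.45 with a mean of at least 20 CPM and -1.88 with at least 5 CPM in 3 samples (camera adjusted p = 0.0485, adjusted p = 0.298 with an estimated correlation). That call also ended with RLE (adjusted p 0.052) and upper quartile scaling (0.0531), and in 4 of the 6 fits without 1 library (0.053 to 0.0835).

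Ribosomal protein genes gave 0 higher and 0 lower of 76 over all genes and 52 and 0 adjusted over the list alone. Their median was 1.17, or 2.09 with total-count scaling (camera adjusted p = 1.12e-11, adjusted p = 0.41 with an estimated correlation). Rpl12 stood at 126 ± 19.1 CPM in WT and 509 ± 194 CPM in Hnrnpu-cKO (SD, n = 3). Many processed copies of these genes exist in the genome, so their single values are uncertain. The 15 mitochondrially encoded genes gave 0 higher and 0 lower, 0 and 0 adjusted over the list alone. The list median was -1.10, or -0.38 with total-count scaling and -0.71 without Hnrnpu-cKO replicate 1 (camera adjusted p = 2.79e-05, adjusted p = 0.41 with an estimated correlation). Of 27 male-biased liver genes, 0 were higher and 3 lower, 1 and 13 adjusted over the list alone. As a set they had a median of -3.12 (camera adjusted p = 4.69e-05, adjusted p = 0.511 with an estimated correlation). Those that fell were Slco1a1, Mup21 and Mup3. The female library stands in the group labelled WT, in which male-biased genes were higher.

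**Figure D4:**
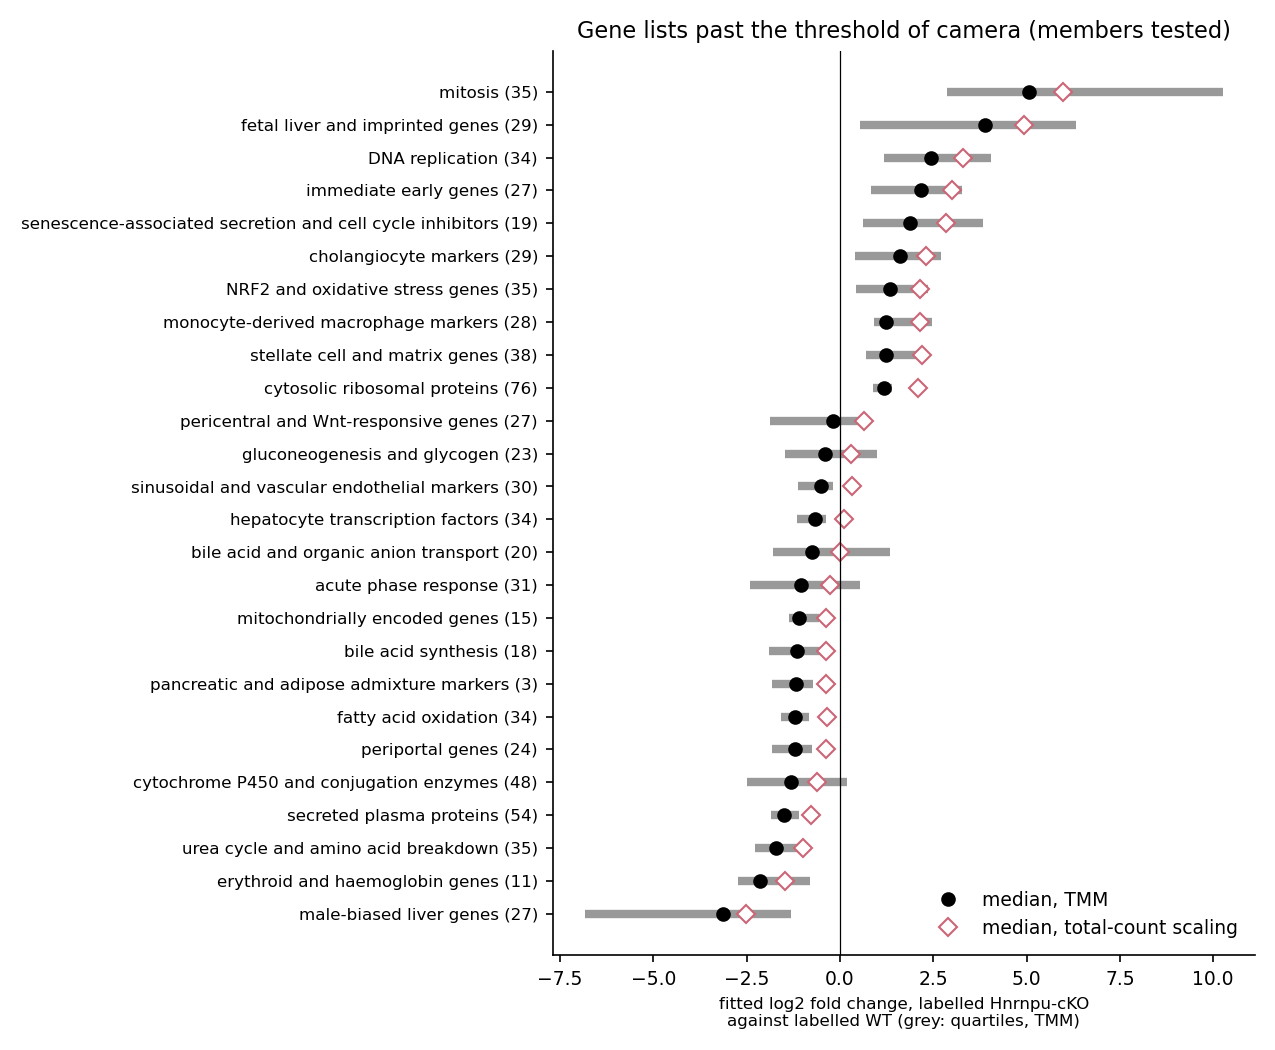
Median fitted log2 fold change, libraries labelled Hnrnpu-cKO against libraries labelled WT, of the 26 lists past the threshold of camera with a preset correlation; filled circles are medians with TMM, grey lines the quartiles of the members, open diamonds the medians with total-count scaling, and numbers in brackets the members tested. The median of mitosis genes is 5.06, and the medians of 5 lists (bile acid and organic anion transport, hepatocyte transcription factors, endothelial markers, gluconeogenesis, pericentral genes) lie below 0 with TMM and above 0 with total-count scaling.

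Among the lists that camera did not call, the other hnRNP genes (33 tested, median log2 fold change 0.42), the core spliceosome (41, 0.57), and SR proteins and splicing regulators (42, 0.09) gave 0 genes higher and 0 lower, and 0 and 0 adjusted over the list alone. Camera called the other hnRNP genes higher with total-count scaling (median 1.27, adjusted p 0.00406) and with a mean of at least 20 CPM (0.40, 0.0151). It called the core spliceosome higher with total-count scaling (1.41, 0.0294) and with at least 5 CPM in 3 samples (0.50, 0.0304). The p53 target list gave 1 higher gene of 30, Mdm2 (log2 fold change 1.77, SE 0.26), and 2 higher and 1 lower adjusted over the list alone. The interferon (41 tested, median 0.01), cholesterol synthesis (25, 0.96), nuclear respiratory chain (47, 0.06), NF-kB (27, 0.25), YAP (26, 0.44), Kupffer cell (18, 0.39), B and plasma cell (20, -0.15), circadian (19, 0.69) and Y-linked (4, 0.48) lists gave 0 genes in either direction, also adjusted over the list alone. Of these, cholesterol synthesis was called higher with at least 5 CPM in 3 samples (median 0.89, adjusted p 0.0154), a mean of at least 20 CPM (1.45, 0.0241), total-count scaling (1.68, 0.0313), without WT replicate 1 (1.72, 0.0179) and without Hnrnpu-cKO replicate 1 (1.36, 0.000115). The NF-kB list was called higher with no filter (0.69, 0.0311) and by fry (0.00433), and the Y-linked list without WT replicate 1 (1.97, 0.027). Interferon genes were called lower without WT replicate 3 (-0.03, 0.0288) and without Hnrnpu-cKO replicate 3 (-0.05, 0.0355). Adjusted over the list alone, the lists of growth factors (39 tested), fatty acid synthesis (28) and T and NK cells (17) gave 4 higher and 4 lower, 7 and 2, and 2 and 0, against 0 and 0 over all genes. The neutrophil list (12 tested) gave 1 higher gene, Slpi, and the female-biased list (28 tested) 1, Sult1e1, with 2 and 1, and 3 and 1, adjusted over the list alone. The female-biased median of -1.71 turned to 2.30 without WT replicate 3.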

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

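Leaving out 1 library ended between 98 and all 204 of the calls: the number of higher genes ranged from 0 to 107 and of lower genes from 0 to 43, and was 0 in both directions without Hnrnpu-cKO replicate 1, 2 or 3, which also leaves fewer samples (3 and 0 without WT replicate 1, 107 and 40 without WT replicate 2, 65 and 43 without WT replicate 3). All 204 calls kept their sign in every one of these fits. Since the groups did not overlap in any of these genes, the sign could hardly turn and does not show stability. Hnrnpu had a positive log2 fold change in all 18 alternatives, from 0.94 to 1.87, with adjusted p from 0.00325 to 0.244; it passed 0.05 with DESeq2 (1.06), limma-voom (1.10), total-count scaling (1.87) and voom with sample quality weights (1.05), and in no other.

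Genes higher and lower numbered 270 and 210 without a filter, 198 and 210 with at least 5 CPM in 3 samples, 270 and 335 with a mean of at least 20 CPM, 1113 and 898 with DESeq2 (all 204 main calls among them), 978 and 447 with limma-voom, 1325 and 835 with sample quality weights, and 1732 and 127 with total-count scaling. At an adjusted p under 0.01 edgeR called 0 and 0, against 3113 at an unadjusted p under 0.05. Total-count scaling, the mean filter, the robust fit and the quality weights were chosen after seeing the data. The causes were not tested. RLE, upper quartile, robust and mitochondria-free fits stayed within 1.5 times of 113 and 91.

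With the replicate block 24 genes were higher and 28 lower, 44 of them shared with the main calls. The female-biased list was called lower by camera (adjusted p 0.0152). Same-numbered libraries had correlations of deviations of -0.011, -0.031 and 0.036, against -0.052 to 0.051 for libraries with different numbers. These values give no sign of pairing by number but cannot exclude it. Lists higher and lower fell from 10 and 16 to 0 and 0 with an estimated correlation. By fry 14 lists were called, and 5 of them were lower, with the urea cycle list at an adjusted p of 0.0113 and plasma proteins at 0.0261. The rest were higher, with mitosis and DNA replication at 0.00433 each by fry, and included the NF-kB list that camera had not called. Of the values of single lists under the alternatives, 647 kept their side of the threshold, 50 lost a call and 15 gained it. For named genes these were 340, 85 and 13, and no called value reversed. The observed spread limits calls to large changes: 4% of simulated changes of 2 on the log2 scale were found.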

Other observations

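The tests of scaling, of more cells other than hepatocytes, of a lower hepatocyte share, of an exchange of labels, of sequencing depth, of distinct molecules and of genes switched off in WT liver were chosen only after the result was seen, while those of sex and of other splits were set before their results were seen. Of the 204 called genes, 134 are on none of the fixed lists, and the genes named only in this paragraph and the next were chosen after their values were seen. In the libraries labelled Hnrnpu-cKO, several called genes on no list rose. Slc7a1 and Slc7a3, transporters of basic amino acids, had 0 counts in every library labelled WT and were at least 101-fold and at least 82.3-fold higher. Slc7a5 had 1 count over the libraries labelled WT and stood at 22.7 ± 9.52 CPM (SD, n = 3) in Hnrnpu-cKO, and its partner chain Slc3a2 rose by 2.42 on the log2 scale (SE 0.39). Aldh18a1, of proline synthesis, and the mitochondrial Pck2 rose as well, Pck2 from 11.9 ± 4.06 to 391 ± 277 CPM. The fixed list of unfolded protein and integrated stress response genes held 4 of the called rises among 32 tested genes, Phgdh, Asns, Atf3 and Nupr1, and 10 adjusted over the list alone, with 0 lower. It was not called as a list (camera adjusted p = 0.57), and Ddit3 stood at 25.4 ± 8.05 CPM in WT and 36.9 ± 6.96 CPM in Hnrnpu-cKO. Nupr1 varied between the libraries labelled Hnrnpu-cKO, at 1473 CPM in replicate 1 against 442 and 384 CPM in the others.

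Krt8, a keratin of simple epithelia, rose from 77.5 ± 32.0 to 730 ± 375 CPM (SD, n = 3), S100a11 from 6.68 ± 3.34 to 123 ± 37.1 CPM, Anxa2 from 10.4 ± 3.35 to 172 ± 123 CPM, and the tubulin genes Tuba1b and Tubb6 by 2.69 and 3.13 on the log2 scale. Of the imprinted Dlk1 and Meg3 cluster, Rian and Dlk1 (at least 47.9-fold higher) passed the test, and Meg3 stood at 11.5 ± 11.7 CPM in WT and 246 ± 132 CPM in Hnrnpu-cKO (adjusted p 0.0675 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the falls, Ahcy and Cdo1, enzymes of methionine and cysteine metabolism, had log2 fold changes of -2.29 (SE 0.36) and -2.42 (SE 0.35). Hsd11b1, which reactivates glucocorticoids, had -3.82 (SE 0.55). In 5 equal groups of genes by exon length the median log2 fold changes ran from 0.18 to 0.26.

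Hnrnpu was not lower in the libraries labelled Hnrnpu-cKO. Among the 500 tested genes nearest in mean level Hnrnpu lay at percentile 88.2, between the bounds set for the test of scaling, which gave no verdict. A ratio was then added as a second criterion after the results were seen. The ratio of Hnrnpu to the other hnRNP genes of the same library, which no scaling alters, was 15.9 ± 3.8% against 8.8 ± 1.7% (SD, n = 3). It argues against scaling between the groups as the whole cause, though the highest WT library (10.5%) lay close to the lowest Hnrnpu-cKO library (12.2%). A lower share of hepatocytes would, as the only change, raise the markers of all other cells alike. Against this, endothelial markers had a median log2 fold change of -0.51 (95% bootstrap interval -0.92 to -0.32) and macrophage markers 1.24 (1.01 to 2.06). These intervals are over the genes of a list, not over libraries, and 0 of 30 endothelial genes passed the test. A lower share together with changes in the other cells could not be excluded in this way. A gain of the cell types whose markers were higher stays open, with medians of 1.60 (0.53 to 2.56) for cholangiocyte and 1.23 (0.95 to 1.71) for stellate cell markers. Kupffer cell markers had a median of 0.39 (-0.19 to 1.12). The test asked only whether any of these medians reached the log2 fold change of Hnrnpu. It cannot decide the question, since marker medians do not tell how much Hnrnpu those cells hold. An exchange of the 2 group labels stays open too. The lowest library labelled Hnrnpu-cKO was 1.48 times the highest labelled WT, but this restates the pattern and is no separate support. A transcript that is still made outside the deleted exons, which counts per gene could not show, stays open as well.

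Fewer genes were detected in the libraries labelled WT. Sequencing depth is argued against, because at equal counts outside the mitochondrial genes the group means still differed by 5967 genes without overlap. Genes switched off in WT liver stay open. Of 9574 genes with at least 100 counts in every library labelled Hnrnpu-cKO, 73 were at 0 in all 3 labelled WT. The other way round it was 1 of 6040. These counts were not thinned. The libraries labelled Hnrnpu-cKO held more counts outside the mitochondrial genes, so their cut of 100 counts admits genes of lower level. Fewer distinct molecules behind the WT libraries may account for the pattern: genes with 1 to 9 counts made up at most 12.48% of their detected genes against at least 19.54% in Hnrnpu-cKO. Fewer molecules would also put genes at 0 in WT, so the 73 do not separate the 2 explanations.

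The calls between the groups may owe something to the sex of WT replicate 3 or to chance. Without WT replicate 3 the log2 fold changes of the 204 called genes were a median of 1.009 times those with it (quartiles 0.985 and 1.051). In the median the size of these changes thus rested little on that library. The genes were called with that library included, which favours genes on which it lay near the other WT libraries. A median ratio near 1 was therefore likely beforehand. All kept their sign, which their lack of overlap between the groups all but fixed in advance. The test cannot exclude sex as a source of calls, since genes on which WT replicate 3 stood apart were less likely to be called. Mup17, on which it stood apart, was called all the same. The number of calls fell to 108, with 61 of them shared. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: 1 of 10 gave as many genes as the real split, the real one with 204, and the highest of the others gave 0. For the lists 1 of 10 did, the real one with 26, and the highest of the others gave 24. The genotype stays open as the source of the calls, with the library differences described above confounded with it.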
